A study of Homo sapiens with 8 samples.

How the data were processed

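RNA was measured in SUM159 breast cancer cells with shCon or shFoxO1, in DMSO or 10 uM olaparib for 3 days, per the labels, which list 2 libraries for each of 4 groups. Total RNA was depleted of ribosomal RNA and made into directional paired-end libraries, per the labels' protocols, so RNA without a poly(A) tail, such as histone mRNA, could be measured. The protocol text names 2 sequencing providers without saying which library went to which, so a batch of that kind can be neither assigned nor removed. CASAVA 1.4, HISAT2 2.1.0 and Cufflinks 2.2.1 and the build hg38 are named in the submitters' processing notes, without roles or settings.

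The authors deposited 2 comparison tables of 60595 genes each. Per the file headers, the authors gave for each gene an FPKM value of each group, a test statistic used here as a score, a p-value and a q-value, and a status. FPKM divides fragments by transcript length and sequencing depth, so the values depend on the authors' length models and on which transcripts take up the reads. That both libraries of a group entered its value is not stated. The authors' deposited q-values equal Benjamini-Hochberg adjustment of the p-values over the genes with status OK, within 5.22e-07. Their smallest p was 5e-05, held by 2610 genes in the first table and 3001 in the second, so genes past that point cannot be ranked by p. Not tested by the authors were 45741 genes in the first table and 45922 in the second, and 13 in each had too many reads. The lowest FPKM of the higher group among tested genes was 0.724 in the first table and 0.868 in the second. Of the untested genes, 5 and 11 had at least 10 FPKM in a group. Spreadsheet software had turned 27 gene symbols into dates in each table, 19 of them of tested genes, and these genes were counted but not named. Of the tested genes of the first table, 72.0% were listed with the same region as another gene, which does not show that they share reads. How the authors' software divided reads between overlapping genes or near-identical copies cannot be checked.

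The group shCon olaparib is in both tables. Its values in the second table were 1.017 times those of the first at the median over 13688 genes of at least 1 FPKM in both (98% of genes between 1.015 and 1.019), so the tables were scaled separately, and tests were read only within a table. No table column held values of other samples (0 columns left out). Depth is unknown, since no counts or library values were used here. The design fixed before the data were examined called for limma on values per library, with camera on that fit for the gene lists. With 1 value per group neither could be fitted, so the calls are those of the authors' deposited q-values at 0.05, and the comparison of each list with random lists was chosen in camera's place after the data were seen.

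Log2 ratios were computed from the deposited FPKM with no pseudocount, and no ratio was computed where a group was at 0 (174 tested genes in the first table, 232 in the second). Gene lists, 28 in all, were written before the data were examined. For each list with at least 5 tested members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, which describes these values and is no test across libraries. Members called over all tested genes were counted, and again after Benjamini-Hochberg adjustment of the authors' p-values over the list alone. limma's camera, run on the authors' test statistic with the preset correlation of 0.01 and adjusted by Benjamini-Hochberg over 25 lists, was an alternative. An estimated correlation needs values per library and could not be had. Simulated data with the spread of the olaparib comparison (14667 genes) put 3 of 100 lists of 25 unchanged genes outside the central 95%, 70 of 100 with a log2 shift of 0.5 and 99 of 100 with a shift of 1. With the spread of the shFoxO1 comparison (14428 genes) the numbers were 6, 53 and 97. Each gene was drawn independently from a normal distribution, so these numbers need not hold for lists whose members move together.

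The named genes were FOXO1, STAT3, TOP2A, PARP1 and PARP2; the 10 largest rises and 10 largest falls in log2 ratio among called genes with a gene symbol of the usual form and a mean of at least 1 FPKM; and from each list described the 2 tested members with the smallest p, up to 4 in all. The symbol was read as that of a RefSeq protein-coding gene, and ties at the smallest p were broken by the larger statistic, details settled after the data were seen. The rule asked for groups whose libraries do not overlap, which cannot be read from 1 value per group. Genes named as not called, as the few exceptions of a list or as markers, and the other list members named beyond the rule, were chosen after their values were seen. Symbols were matched to RefSeq of GRCh38.p14, the same build as hg38, for 88.5% of the genes tested in the first table, and 100% of the matched positions, after rounding, overlapped the listed regions.

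The relation of the comparisons was simulated 100 times with unchanged groups, with the standard error that each authors' p-value implies for its log2 ratio. Alternatives were pseudocounts of 0.01, 0.1 and 1, other filters and thresholds, quantile normalization and median of ratios scaling of group values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.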

Results

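The series measured RNA in SUM159 cells, an established human triple-negative breast cancer line, with or without olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2. Cells carried a control shRNA (shCon) or an shRNA against FOXO1 (shFoxO1), a transcription factor restrained by insulin and AKT signalling, and were held for 3 days in the solvent DMSO or in 10 uM olaparib. The labels list 8 libraries in 4 groups of 2. Of these groups, 3 were analysed, and shFoxO1 cells in DMSO were not analysed here. The deposited values form 2 tables, 1 setting olaparib against DMSO in shCon cells and 1 setting shFoxO1 against shCon under olaparib. Each table gives 1 FPKM value per gene and group, so no spread between libraries can be shown, no SD or n of libraries stands beside a value, and the depth behind the values is unknown. Genes are called higher or lower where the q-value in the authors' deposited table was at most 0.05. The labels do not say whether the 2 libraries of a group came from separate cultures, so these q-values may measure technical spread.

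The purpose given for the series was to find a marker of sensitivity to PARP inhibitors and the targets of FOXO1, STAT3 and TOP2A. FOXO1 itself (ENSG00000150907, chromosome 13, 40555667 to 40666641 in GRCh38.p14) was at 54.6 FPKM in shCon cells in DMSO and 87.7 FPKM in shCon cells under olaparib, a difference that did not pass in the authors' deposited table (q = 0.0966); the log2 ratio was 0.68, and 1.05 after quantile normalization. Under olaparib it fell from 89.2 FPKM with shCon to 17.5 FPKM with shFoxO1, a 5.11-fold decrease (log2 ratio -2.35, q = 0.000244 in the authors' deposited table), in the direction the shRNA label names. TOP2A (ENSG00000131747, chromosome 17, 40388525 to 40417896), the topoisomerase of dividing cells, rose 3.83-fold with olaparib, from 39.3 to 151 FPKM (q = 0.000284 in the authors' deposited table). With shFoxO1 under olaparib it fell 4.02-fold, from 153 to 38.2 FPKM (q = 0.000244 in the authors' deposited table). STAT3 was not called in either comparison, at 38.6 and 30.4 FPKM without and with olaparib (q = 0.0645 in the authors' deposited table) and at 30.9 and 38.0 FPKM with shCon and shFoxO1 (q = 0.119). Among the drug's targets, PARP1 fell from 73.7 to 51.1 FPKM with olaparib (log2 ratio -0.53, q = 0.00186 in the authors' deposited table), a ratio that shrank to -0.17 after quantile normalization. With shFoxO1 PARP1 was at 52.7 FPKM against 52.0 FPKM. PARP2 was not called with olaparib, at 26 and 22.4 FPKM, and rose from 22.9 to 37.5 FPKM with shFoxO1 (q = 0.00106 in the authors' deposited table).

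**Figure D1:**
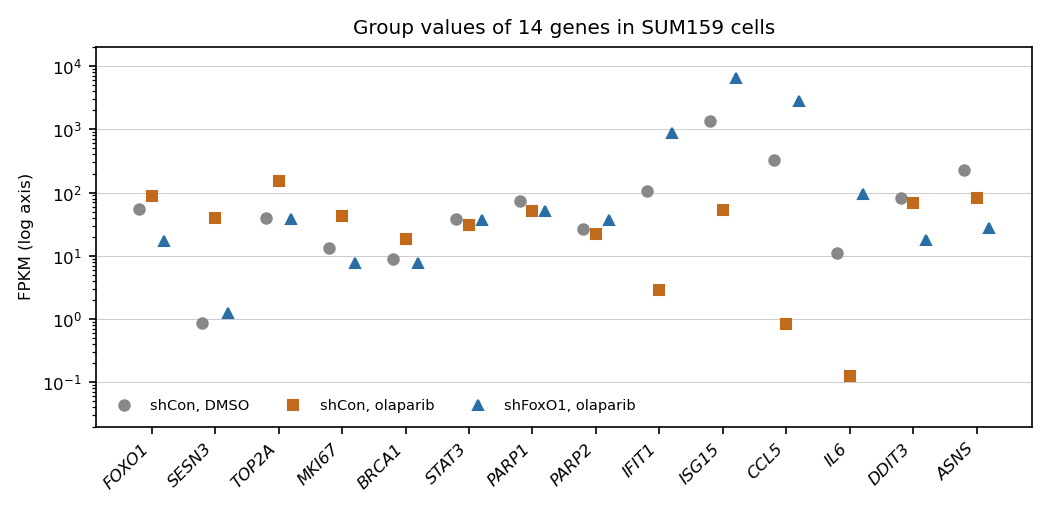
FPKM of 14 genes (log axis) in shCon cells in DMSO, shCon cells under olaparib and shFoxO1 cells under olaparib, 1 value per group with no error bar. The last group comes from the second table and was divided by 1.017, the ratio of the values both tables give for shCon cells under olaparib. FOXO1 and TOP2A are highest in shCon cells under olaparib, at 87.7 and 151 FPKM, while CCL5 and IL6 are lowest there, at 0.836 and 0.125 FPKM.

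The first comparison asked which genes olaparib changed in control cells. After 3 days of the drug, most tested genes of mitosis were higher, as were some of the histone, homologous recombination and DNA replication genes, of which the larger part did not pass. Most inflammatory cytokines, interferon-stimulated genes and genes of the unfolded protein response were lower. Of 14841 tested genes, 2311 were called higher and 3433 lower. At least 2-fold changes were seen in 1266 of the higher and 1445 of the lower genes. The median log2 ratio of all tested genes was -0.07.

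The 10 largest rises among named genes with a mean of at least 1 FPKM were in MAT1A, CELF6, STOX1, SESN3, STARD8, CRISP3, RANBP3L, SLC6A3, PPP1R14C and MLIP, with log2 ratios from 4.93 to 6.48. SESN3, a stress-induced regulator of mTORC1 signalling, rose from 0.857 to 39.0 FPKM (q = 0.000284 in the authors' deposited table), and SLC6A3, the dopamine transporter, from 1.23 to 40.0 FPKM. The 10 largest falls, with log2 ratios from -8.62 to -6.23, included CCL5, TMEM255B, MEST, COL6A2, ZACN, CHST15, IL6, GBP4 and OAS2. CCL5, a chemokine for T cells and monocytes, fell from 328 to 0.836 FPKM (q = 0.000284 in the authors' deposited table). COL6A2, a collagen VI chain, fell from 25.4 to 0.224 FPKM, and the imprinted gene MEST from 10.3 to 0.0837 FPKM. Several of these genes were near 0 in a group, and on the log2(FPKM + 1) scale the ranges narrowed to 1.62 to 4.43 for the rises and -7.49 to -1.59 for the falls. With every listed gene entered in the adjustment, 6 of these 20 calls were lost, among them those of MAT1A, CELF6, STOX1, TMEM255B and ZACN.

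Genes of mitosis moved up together with olaparib: 20 of 31 tested members were called higher and none lower, the same counts when adjusted over the list alone. Their median log2 ratio of 0.66 lay above every one of 10000 random lists of the same size and expression. ASPM, a spindle pole protein, rose from 3.57 to 18.5 FPKM, MKI67, the proliferation antigen Ki-67, from 13.2 to 42.4 FPKM and CENPF from 5.88 to 33.5 FPKM. PLK1 and AURKA were not called, at 91.2 and 45.4 FPKM under olaparib against 103 and 48.3 FPKM in DMSO. Among 39 genes of homologous recombination and the Fanconi anaemia pathway, 10 were called higher and 1 lower (also 10 and 1 adjusted over the list alone), with a median of 0.28 (0.43 after quantile normalization) at percentile 99.4 of the random lists and 28 members not called. SLX4, a scaffold of structure-specific nucleases, rose from 3.18 to 7.06 FPKM, BRIP1 from 3.03 to 8.60 FPKM and BRCA1 from 8.82 to 18.6 FPKM. The BRCA1 call (q = 0.0258 in the authors' deposited table) would be lost with every listed gene entered in the adjustment. MUS81 fell from 44.4 to 19.8 FPKM. Of 39 DNA replication genes, 8 were called higher and 3 lower (8 and 2 adjusted over the list alone), with 28 not called and a median of 0.18 (0.40 after quantile normalization) at percentile 99.9. The licensing factors ORC1, from 8.72 to 29.5 FPKM, and CDT1, from 54.5 to 118 FPKM, were among those that rose. Replication-dependent histones had 13 of 33 members called higher and 1 lower (15 and 1 adjusted over the list alone), median 1.36 (0.90 with a pseudocount of 1), above every random list. HIST1H1C rose from 21.5 to 76.7 FPKM and HIST2H2BE from 2.12 to 8.93 FPKM. Near-identical histone copies share reads, so values of single histone genes are uncertain. Cytosolic ribosomal protein genes had 9 of 76 members called higher and none lower (5 and none adjusted over the list alone), with a small median of 0.16. Of all 14841 tested genes, 2311 were called higher and 3433 lower. The share of ribosomal genes called higher was thus below that of all genes, and the share of DNA replication genes only somewhat above it. RPL7 rose from 1073 to 1826 FPKM and RPL34 from 1418 to 2042 FPKM. After quantile normalization the ribosomal median of 0.11 lay at percentile 96.3, no longer outside the central 95% of random lists.

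Inflammatory genes moved the other way. Of 18 tested NF-kB targets and inflammatory cytokines, 17 were called lower with olaparib and none higher, also 17 when adjusted over the list alone, with a median of -2.72 below every random list. BIRC3, an inhibitor of apoptosis, fell from 94.0 to 4.58 FPKM, NFKB2 from 71.4 to 17.0 FPKM, IL6 from 11.2 to 0.125 FPKM and CXCL8 from 20.3 to 0.358 FPKM. Of 32 interferon-stimulated genes, 18 were called lower and 2 higher (19 and 2 adjusted over the list alone), with a median of -1.17 below every random list. ISG15, a ubiquitin-like modifier, fell from 1366 to 52.3 FPKM, OASL from 508 to 14 FPKM and IFIT1 from 107 to 2.84 FPKM. The 2 that rose were STAT2, from 25.7 to 45 FPKM, and IFI44L, from 4.51 to 14.2 FPKM. CXCL10 went from 27.9 to 0.0475 FPKM and was not called (q = 0.277 in the authors' deposited table). Among leukocyte markers, PTPRC went from 1.34 FPKM in DMSO to 0.142 FPKM under olaparib and was not tested. CD14 went from 0.865 to 0.350 FPKM and CD68 from 18.2 to 14.9 FPKM, neither called, and LYZ, CD3D and MS4A1 were listed at 0 in both.

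Of 20 genes of the unfolded protein response and the ATF4 programme, 15 were called lower and none higher, also 15 adjusted over the list alone, with a median of -0.93 (-0.61 after quantile normalization) at percentile 0.03. CHAC1, a glutathione-degrading enzyme, fell from 45.4 to 7.87 FPKM, and TRIB3, a pseudokinase induced by ATF4, from 397 to 113 FPKM. The chaperone HSPA5 was not called, at 127 and 118 FPKM. Immediate early genes had 12 of 16 members called lower and none higher (also 12 adjusted over the list alone, median -0.82, or -0.55 after quantile normalization, percentile 0.15), among them FOSL1, from 126 to 11.4 FPKM, and IER3, from 149 to 31.9 FPKM. STAT3 targets had 16 of 23 members called lower and 3 higher (16 and 3 adjusted over the list alone, median -0.81, percentile 0.06). SOCS3, the feedback inhibitor of STAT3 signalling, fell from 10.7 to 2.61 FPKM and MCL1 from 251 to 109 FPKM, a log2 ratio of -1.20 that shrank to -0.77 after quantile normalization. The BCL2 family had 9 of 13 members called lower and 2 higher (9 and 2 adjusted over the list alone, median -0.83, percentile 0.25), with PMAIP1, which encodes the death protein NOXA, going from 37.3 to 6.20 FPKM and BAK1 from 32.2 to 9.08 FPKM. Hypoxia and glycolysis genes had 8 of 20 called lower and 2 higher (9 and 3 adjusted over the list alone, median -0.60, percentile 0.65). ANGPTL4 fell from 62.2 to 9.43 FPKM, while EGLN3 rose from 12.3 to 39.9 FPKM.

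FOXO targets split evenly under olaparib, with 11 of 26 called higher and 11 lower, the same counts when adjusted over the list alone. Their median of 0.39 lay above every random list, but camera on the authors' test statistic gave an adjusted p of 0.734. SESN1 rose from 10.5 to 53.6 FPKM along with SESN3, and CCNG2 from 7.77 to 33.6 FPKM, while SOD2 fell from 712 to 158 FPKM and KLF2 from 16.3 to 4.21 FPKM. The p53 pathway was also divided, with 7 of 25 members called higher and 11 lower, the same adjusted over the list alone. BTG2 rose from 3.47 to 19.2 FPKM, and AEN, an apoptosis-enhancing nuclease, fell from 35.8 to 6.19 FPKM. That list's median of 0.02 stood at percentile 80.6 of the random lists.

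The other lists stayed within the central 95% of random lists, except small nuclear and nucleolar RNAs. End joining and shieldin genes had 3 of 15 called higher, POLQ (2.35 to 7.18 FPKM) and RIF1 (3.5 to 6.50 FPKM) among them, and 4 lower. PARP family and single-strand break repair genes had 1 of 15 called higher and 6 lower, with ADPRHL2 going from 27.0 to 15.7 FPKM and PARP4 from 16.9 to 10.3 FPKM. Besides TOP2A, TOP2B rose from 20.9 to 36.8 FPKM and 1 of the 8 topoisomerases was called lower. Cholesterol synthesis had 7 of 22 called higher and 6 lower, and INSIG1 rose from 7.97 to 25.1 FPKM. NRF2 targets had 4 of 17 called higher and 11 lower, with FTH1, ferritin heavy chain, falling from 2603 to 931 FPKM and TALDO1 from 220 to 112 FPKM, the latter a log2 ratio of -0.97 that shrank to -0.53 after quantile normalization. Mesenchymal and matrix genes had 3 of 25 called higher and 13 lower, with COL1A1 falling from 129 to 7.16 FPKM, and camera called the list lower (adjusted p = 0.00207). Insulin and PI3K-AKT signalling had 4 of 19 called higher and 5 lower, IRS2 falling from 19.4 to 7.62 FPKM and PIK3R1 rising from 68.5 to 159 FPKM. Drug efflux transporters had 3 of 7 called lower, ABCC2 from 7.45 to 1.34 FPKM and ABCG2 from 3.56 to 0.833 FPKM among them. Luminal breast markers had 3 of 5 called lower, XBP1 (253 to 88.1 FPKM) and GATA3 (15.0 to 8.68 FPKM) among them. Adjusted over the list alone, the counts of these 9 lists were the same except for mesenchymal genes, with 4 higher. Among mitochondrially encoded mRNAs 1 of 13 was called higher, MT-ND1, and 1 lower, MT-CO2, which fell from 8538 to 5362 FPKM. Both were also called adjusted over the list alone, but the MT-ND1 call was lost with every listed gene entered in the adjustment. Of 16 tested genes in the list of small nuclear and nucleolar RNAs, which also takes in the cytoplasmic 7SL RNA (RN7SL) and copies of it, 1 was called higher and 1 lower (1 and 0 adjusted over the list alone), RN7SL2 at 275 and 730 FPKM and RN7SK at 27.1 and 13.9 FPKM, with a median of 0.82 at percentile 99.6 that camera did not call (adjusted p = 0.239). Epithelial, leukocyte and endothelial lists had fewer than 5 tested members. CDH1 was listed at 0 in all 3 groups. The median and mean differed in sign for topoisomerases (-0.11 and 0.18), cholesterol synthesis (-0.07 and 0.11), mitochondrial mRNAs (-0.02 and 0.01) and PI3K-AKT signalling (0.12 and -0.07). Camera put these 4 lists higher, none past its threshold, and quantile normalization turned the medians of the first 3 to 0.08, 0.13 and 0.07.

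**Figure D2:**
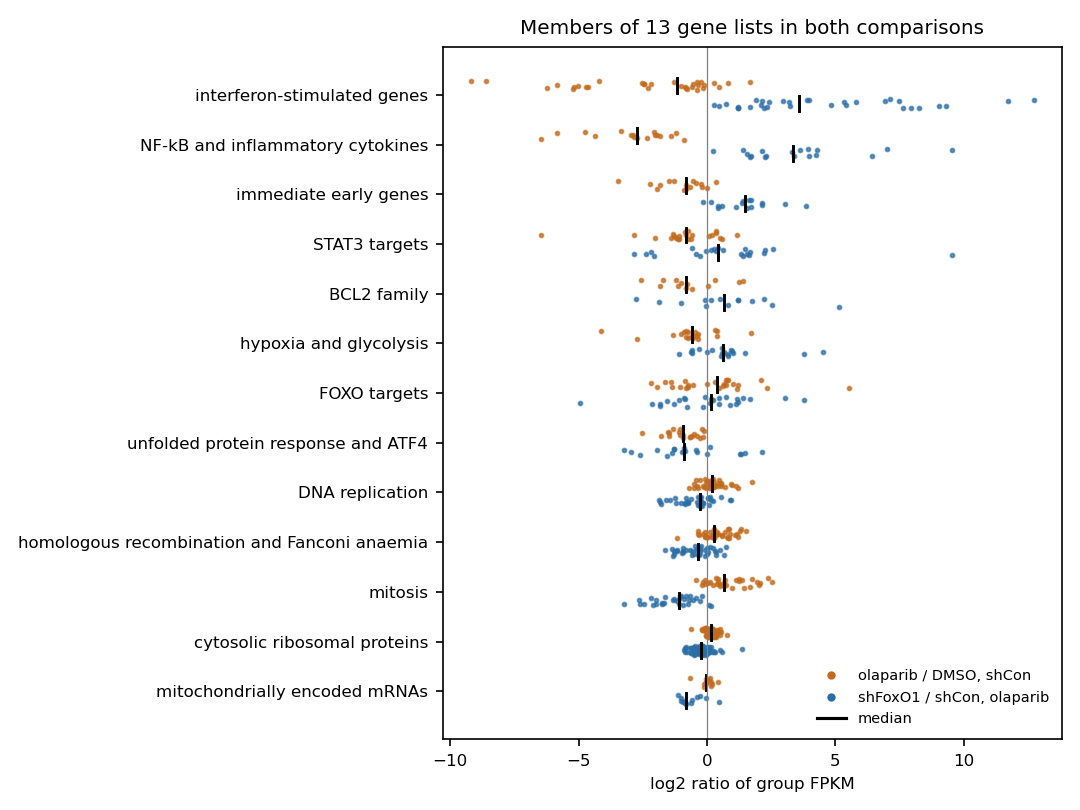
Log2 ratio of group FPKM for each tested member of 13 gene lists, with olaparib against DMSO in shCon cells in orange, shFoxO1 against shCon under olaparib in blue, and the list median as a black bar. Interferon-stimulated genes have medians of -1.17 and 3.57, mitosis genes 0.66 and -1.11, and genes of the unfolded protein response and ATF4 are lower in both, at -0.93 and -0.91.

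The second comparison asked which genes differed with shFoxO1 under olaparib. Most interferon-stimulated and inflammatory genes were higher with shFoxO1, with median log2 ratios of 3.57 and 3.35 (the latter 1.99 with a pseudocount of 1), and most mitosis genes were lower. Of 14660 tested genes, 3314 were called higher and 2904 lower. At least 2-fold changes were seen in 1737 of the higher and 1731 of the lower genes. The median log2 ratio of all tested genes was 0.01.

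The 10 largest rises included CCL5, KLRD1, IL6, OAS2, RSAD2, GBP4, PRSS23, IFIT1 and IFIT3, with log2 ratios from 7.96 to 11.72. CCL5 rose from 0.851 to 2878 FPKM, IL6 from 0.127 to 95.4 FPKM and RSAD2, the antiviral protein viperin, from 0.552 to 292 FPKM. The 10 largest falls were in PAPPA2, AZGP1, FIBIN, CELF6, CYP4B1, VAT1L, CIDEC, RUNDC3B, DNAJC22 and IL16, with log2 ratios from -9.48 to -6.01. CYP4B1, a cytochrome P450, fell from 508 to 4.66 FPKM, CIDEC, a lipid droplet protein, from 147 to 2.08 FPKM, and AZGP1 from 74.3 to 0.254 FPKM. On the log2(FPKM + 1) scale the rises spanned 4.01 to 10.60 and the falls -6.49 to -1.80. With every listed gene entered in the adjustment, the calls of FIBIN and CELF6 were among those lost.

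Of 34 tested interferon-stimulated genes, 31 were called higher with shFoxO1 and none lower, also 31 adjusted over the list alone, and the median of 3.57 lay above every random list. ISG15 rose from 53.2 to 6544 FPKM, OASL from 14.3 to 2512 FPKM and IFIT1 from 2.89 to 880 FPKM. The 3 not called were BST2, IFI44L and CXCL10, the last of these in spite of an FPKM of 322 on the first table's scale with shFoxO1 (q = 0.276 in the authors' deposited table). NF-kB targets and cytokines had 17 of 19 members called higher and none lower, also 17 adjusted over the list alone, with a median of 3.35 above every random list. BIRC3 rose from 4.67 to 602 FPKM, and TNFAIP3, a feedback inhibitor of NF-kB, from 8.98 to 176 FPKM. NFKB1 was not called, at 24.8 FPKM with shCon and 29.0 FPKM with shFoxO1 on the first table's scale. Immediate early genes had 13 of 16 called higher and none lower (14 and none adjusted over the list alone, median 1.49, above every random list), among them FOSL1, from 11.6 to 169 FPKM, and KLF2, from 4.28 to 34.7 FPKM. Of the markers of other cell types, PTPRC, LYZ, CD3D, CD3E and MS4A1 were listed at 0 in shFoxO1 cells. CD14 was at 0.334 FPKM there and CD68, not called, at 39.3 FPKM. The endothelial marker PECAM1 rose to 1.76 FPKM and the haemoglobin gene HBB to 2.18 FPKM. Of 3 tested endothelial markers, 2 were called higher and 1 lower.

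The BCL2 family had 8 of 15 members called higher and 3 lower (8 and 3 adjusted over the list alone, median 0.66, percentile 98.8). PMAIP1 rose from 6.32 to 220 FPKM and MCL1 from 111 to 513 FPKM. Hypoxia and glycolysis genes had 7 of 20 called higher and 3 lower (7 and 3 adjusted over the list alone, median 0.61, percentile 98.8), with ANGPTL4 going from 9.58 to 217 FPKM and LDHA, lactate dehydrogenase, from 273 to 750 FPKM. STAT3 targets had 12 of 23 called higher and 6 lower, the same adjusted over the list alone. TIMP1 rose from 186 to 1094 FPKM. The STAT3 list's median of 0.43 lay at percentile 92.3, within the central 95% of random lists, and at percentile 97.6 after quantile normalization.

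Genes of mitosis fell together: 25 of 31 were called lower and none higher (26 and none adjusted over the list alone), with a median of -1.11 below every random list. BIRC5, which encodes survivin, fell from 92.1 to 20 FPKM. Of 39 DNA replication genes, 14 were called lower and 2 higher, the same adjusted over the list alone, with a median of -0.28 (-0.47 after quantile normalization) at percentile 0.47. TK1, thymidine kinase, fell from 143 to 40.9 FPKM and CDT1 from 120 to 33.0 FPKM. Homologous recombination and Fanconi genes had 11 of 39 called lower and 1 higher, the same adjusted over the list alone, with a median of -0.34 at percentile 1.57. Camera on the authors' test statistic did not call this list (adjusted p = 0.0604). FANCE fell from 25.9 to 10.1 FPKM and SLX4 from 7.18 to 2.91 FPKM. BRCA1 fell from 18.6 to 7.69 FPKM on the first table's scale. Histones had 8 of 27 members called lower and 3 higher, the same adjusted over the list alone, with a median of -0.98 (-0.60 with a pseudocount of 1) at percentile 0.08 that camera did not call (adjusted p = 0.133). HIST1H3H fell from 11.4 to 2.51 FPKM, whereas HIST1H2AC rose from 13.5 to 39.9 FPKM.

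Genes of the unfolded protein response and ATF4 were lower again, with 13 of 20 called lower and 4 higher (14 and 4 adjusted over the list alone) and a median of -0.91 below every random list. TRIB3 fell from 115 to 12.0 FPKM, and PHGDH, the first enzyme of serine synthesis, from 217 to 27.5 FPKM. ATF4 itself fell from 435 to 220 FPKM on the first table's scale. The 4 that rose were XBP1, SDF2L1, DNAJB9 and ATF3. Mitochondrially encoded mRNAs had 8 of 13 called lower and 1 higher (9 and 1 adjusted over the list alone), with a median of -0.80 below every random list. MT-CYB fell from 4209 to 2089 FPKM and MT-ND1 from 3715 to 1923 FPKM, while MT-CO2 rose. Cytosolic ribosomal protein genes had 21 of 76 called lower and 3 higher (20 and 3 adjusted over the list alone), with a median of -0.23 below every random list, RPL8 going from 2552 to 1410 FPKM and RPS2 from 3821 to 2038 FPKM. After quantile normalization that median was -0.08, at percentile 17.7.

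FOXO targets again went both ways with shFoxO1, 9 of 26 called higher and 10 lower, the same adjusted over the list alone. SESN3 fell from 39.7 to 1.29 FPKM, whereas KLF2, also an immediate early gene, rose. Their median of 0.14 lay at percentile 49.7 and became -0.05 after quantile normalization, while their mean was -0.05 and camera put them lower without passing. Mesenchymal and matrix genes had 7 of 25 called higher and 9 lower (7 and 11 adjusted over the list alone), with a median of -0.44 at percentile 1.26. That list was inside the central 95% after quantile normalization, at percentile 3.22, and camera, which put it higher, gave an adjusted p of 0.772. ITGA5 rose from 78.5 to 547 FPKM. The p53 pathway had 6 of 25 called higher, including AEN (6.30 to 38.1 FPKM), and 11 lower, including BTG2 (19.5 to 2.31 FPKM).

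The remaining lists with at least 5 tested members lay within the central 95% of random lists, except small nuclear and nucleolar RNAs. PARP family and single-strand break repair genes had 7 of 15 called higher, with HPF1, the cofactor of PARP1 in serine ADP-ribosylation, going from 19.6 to 41.3 FPKM and PARP4 from 10.5 to 19.2 FPKM, and 2 lower. End joining and shieldin genes had 2 of 15 called higher, including XRCC5 (79.3 to 133 FPKM, a log2 ratio of 0.74, or 0.49 after quantile normalization), and 1 lower, POLQ (7.31 to 3.93 FPKM). Of the 8 topoisomerases, 1 was called higher and 3 lower, TOP1MT going from 18.7 to 8.93 FPKM. Cholesterol synthesis had 5 of 22 called higher, including NSDHL (8.79 to 18.9 FPKM), and 4 lower. NRF2 targets had 6 of 17 called higher, including FTH1 (946 to 4534 FPKM), and 3 lower, including TXNRD1 (309 to 64.2 FPKM). Insulin and PI3K-AKT signalling had 7 of 18 called higher, IRS2 (7.75 to 24.5 FPKM) and PIK3R3 (9.00 to 31.1 FPKM) among them, and 5 lower. Drug efflux transporters had 4 of 7 called higher, including ABCC2 (1.37 to 11.1 FPKM), and 1 lower, ABCC3 (77.3 to 44.9 FPKM). Luminal breast markers had 1 of 5 called higher, XBP1 (89.6 to 251 FPKM), and 1 lower, KRT8 (331 to 93.7 FPKM). Adjusted over the list alone, these 8 lists and the p53 pathway kept their counts except for NRF2 targets (7 higher, 4 lower), PI3K-AKT signalling (6 lower) and the p53 pathway (12 lower). Of 13 tested genes in the list of small nuclear and nucleolar RNAs, 2 were called lower (1 adjusted over the list alone), both of them 7SL genes, RN7SL2 at 741 and 86.9 FPKM and RN7SL3 at 34.7 and 6.72 FPKM, with a median of -1.21 at percentile 0.05 that camera did not call (adjusted p = 0.249). For PI3K-AKT signalling the median was -0.03 and the mean 0.19, with camera putting the list higher without passing. The end joining median of 0.08 became -0.05 after quantile normalization. Epithelial, leukocyte and endothelial lists again had fewer than 5 tested members. The epithelial list had 1 of 4 called higher and 2 lower, and the leukocyte list 1 of 2 higher and none lower.

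Genes called in both comparisons mostly moved in opposite directions. Among 14134 genes tested in both with values above 0, 3692 were called in both, and 3509 of these (95%) did so. Of the 14134 genes, 2241 were higher and 3337 lower with olaparib, of which 746 and 1140 were not called with shFoxO1, and 3167 were higher and 2846 lower with shFoxO1. Genes higher with olaparib and lower with shFoxO1 numbered 1448, where independent lists of the same sizes would share 451, and genes lower with olaparib and higher with shFoxO1 numbered 2061, where independent lists would share 748. Changes in the same direction were fewer than independent lists would give, 47 higher in both against 502 and 136 lower in both against 672. The log2 ratios had a correlation of -0.76 across genes, which are not independent replicates. Both comparisons use the shCon olaparib values with opposite sign, which alone gives a negative relation: 100 simulations of unchanged groups with the error implied by the authors' p-values gave correlations from -0.59 to -0.44. The covariance was -1.15, against -0.26 to -0.17 in the simulations, and -0.68 among genes with a mean of at least 5 FPKM in both tables. The shared libraries could not be split, so part of the excess may come from them.

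**Figure D3:**
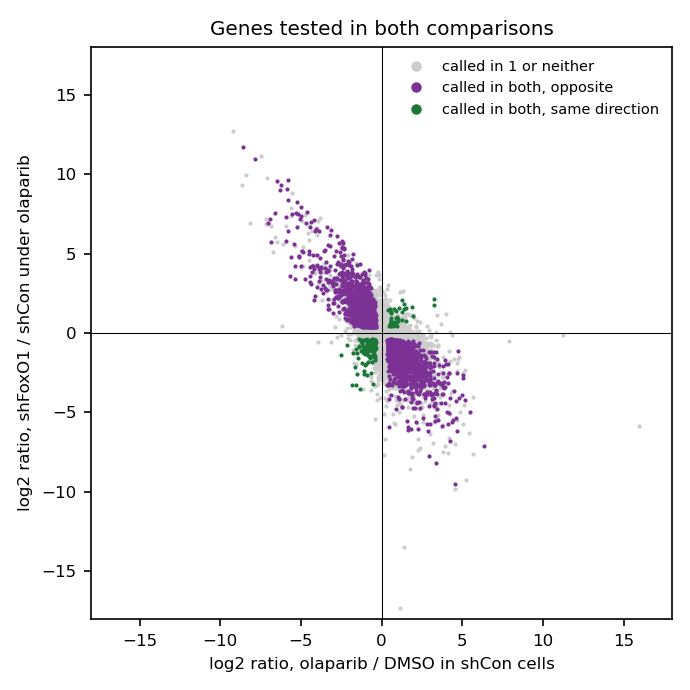
Log2 ratio of olaparib over DMSO in shCon cells (horizontal) against log2 ratio of shFoxO1 over shCon under olaparib (vertical), 1 point per gene tested in both comparisons. The 3509 genes called in both with opposite directions (purple) lie at the upper left and lower right, and the 183 called in the same direction (green) at the lower left and upper right.

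Levels in shFoxO1 cells under olaparib were also set beside those of shCon cells in DMSO. The tables were normalized separately and the values of the first and last group were not tested against each other. The shFoxO1 values were divided by 1.017, the median ratio of the shared group between the tables, to place them on the first table's scale. TOP2A stood at 39.3 FPKM in DMSO and 37.5 FPKM in shFoxO1 cells under olaparib, and SESN3 at 0.857 and 1.26 FPKM. These 2 genes do not stand for their lists. Of 31 mitosis genes, 8 were above and 23 below the DMSO level, with a median log2 ratio of -0.38. Of 26 replication-dependent histones, 17 were above and 9 below it, with a median of 0.49. Interferon-stimulated genes went beyond the DMSO level, with all 32 genes tested in both tables above it and a median log2 ratio of 2.26, and ISG15 at 6432 FPKM against 1366 FPKM. Of 17 NF-kB targets and cytokines, 11 were above and 6 below the DMSO level, with a median of 0.60. The unfolded protein response and ATF4 list was further below DMSO than with olaparib alone, at a median of -1.51.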

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

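Only the authors' group values were at hand, so leaving out a replicate, a joint fit of 6 libraries, a fit without trend, fry, camera with an estimated correlation and a split of the shared libraries could not be run, nor could the direct test of shFoxO1 olaparib against shCon DMSO. No paired analysis was possible because the tables carry no values per replicate. The authors' calls, planned as an alternative, became the main ones. The pseudocount of 1, the filter at 1 FPKM, camera on the authors' statistic, scaling for the lists and the relation among genes of at least 5 FPKM were chosen after seeing the data. A requirement of at least 2-fold lowered the called genes from 5744 to 2711 with olaparib (1266 higher, 1445 lower) and from 6218 to 3468 with shFoxO1 (1737 higher, 1731 lower), by the construction of a stricter threshold. The other filters and q-values at 0.10 gave 4327 to 6562 and 4814 to 7155 genes. The covariance of the comparisons was -0.68 for genes of at least 5 FPKM against -1.15 for all, and the cause was not tested. Lists outside the central 95% numbered 14 in both comparisons, and camera called 13 and 10. Of 200 list medians under a pseudocount or another scaling, 196 stayed on their side of that range, and the 4 others, all under quantile normalization, were the ribosomal list in both comparisons and the mesenchymal and STAT3 lists with shFoxO1. None of 715 log2 ratios of named genes reversed a call, but 26 shrank by more than 1.5 times with a pseudocount of 1, 16 with olaparib and 10 with shFoxO1, ABCG2 to -1.32 among them. Entering all listed genes in the adjustment ended 12 of the calls of genes named by the rule. Among them were those of MT-ND1 and RN7SK with olaparib and RN7SL3 with shFoxO1. Genes named beyond the rule were not put through it, and some of their calls would be lost too. BRCA1 with olaparib is such a gene, since its p in the authors' test was larger than that of MAT1A, whose call was lost. Depth is unknown and sets no limit that can be stated.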

Other observations

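The gene groups in the first 2 paragraphs, and all tests in this part, were chosen after the values were seen. With shFoxO1 under olaparib, 12 of 15 antigen presentation genes were called higher and none lower. B2M, the light chain of MHC class I, rose from 1282 to 4916 FPKM, HLA-B from 247 to 606 FPKM and TAP1 from 39.6 to 113 FPKM. With olaparib in shCon cells 5 of the 15 were called lower, B2M, TAP1 and TAP2 among them, 1 higher (HLA-F) and 9 not called. No test of the group was made, and of all tested genes 3314 of 14660 were called higher with shFoxO1. Among interferon genes, IFNB1, IFNA1, IFNL2 and IFNL3 were listed at 0 in all 3 groups, whereas IFNL1 was at 1.45 FPKM in DMSO, listed at 0 in shCon cells under olaparib, and at 9.81 FPKM in shFoxO1 cells under olaparib on the first table's scale. The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) fell with olaparib, from 22.3 to 1.21 FPKM and from 17.6 to 3.17 FPKM, and rose with shFoxO1 to 169 and 177 FPKM on that scale. The DNA sensor CGAS was not called in either comparison, at 12.7, 10.6 and 10.4 FPKM.

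Circadian clock genes were looked at as a slightly longer list, of which 11 are counted here, so the counts are not those of the whole list. Of these, 6 were called higher with olaparib, 2 lower and 3 (PER2, NR1D1 and BHLHE41) not called. No test of the group was made, and of all 14841 tested genes 2311 were called higher and 3433 lower with olaparib. DBP rose from 2.89 to 19.0 FPKM, TEF from 7.37 to 18.0 FPKM and PER3 from 1.22 to 5.27 FPKM, while ARNTL, which encodes BMAL1, fell from 21.7 to 6.53 FPKM and CRY1 from 7.99 to 2.80 FPKM. These 5 were called in the opposite direction with shFoxO1. SELENOP, a selenium carrier, rose from 3.63 to 79.2 FPKM with olaparib and stood at 1.79 FPKM with shFoxO1 on the first table's scale. FOXO4 rose from 2.24 to 5.68 FPKM and FOXO3 from 24.9 to 38.6 FPKM with olaparib, and with shFoxO1 FOXO4 fell to 2.28 FPKM while FOXO3 was not called, at 42.7 FPKM. ACTB, often used as a reference gene, fell from 2174 to 1263 FPKM with olaparib and rose with shFoxO1 to 2071 FPKM on that scale.

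The genes called in both comparisons mostly went in opposite directions. Chance error in the shared shCon olaparib values, of the size that the authors' test models, was argued against as the main source. At that size the q threshold allows about 287 false calls among all olaparib calls, and 3509 genes went in opposite directions. False shFoxO1 calls made through the same shared values were not counted in the 287. The q-values may measure only technical spread, so a larger error in those values is not covered. A trend with gene span was also argued against, since removing it from both ratios, for the 90.2% of genes with a RefSeq span, left -1.10 of a covariance of -1.12. The opposite share of 95% could come from a response to olaparib that needs FOXO1. Or shCon olaparib cultures may have stood apart for another reason, such as density or handling. A spread between cultures that the authors' test does not carry could be such a reason too. An effect of shFoxO1 on these genes that is also present without the drug is left open as well. These readings cannot be told apart with the groups analysed here, which did not include shFoxO1 cells in DMSO.

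Most interferon-stimulated and NF-kB genes fell with olaparib in shCon cells and rose with shFoxO1, the interferon-stimulated genes beyond their DMSO level. For the rise, RNA from leukocytes would bring abundant leukocyte transcripts, but the highest of PTPRC, CD3E, CD3D, MS4A1, LYZ and CD14 in shFoxO1 cells was 0.334 FPKM. Scaling between groups was argued against, since after quantile normalization both lists kept the sign of their medians outside the central 95% of random lists in both comparisons, the smallest in size being -1.15. A hypothesis is that loss of FOXO1 may release these genes under the drug, but a response to the shRNA or its lentiviral vector could also raise them, and the median log2 ratio of 2.26 to DMSO of the interferon-stimulated genes does not separate these. They cannot be told apart, because neither shFoxO1 DMSO cells nor another FOXO1 shRNA were analysed here.

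The ratio between the tables' values for the shared group showed separate peaks among 3169 genes at 0.02 to 0.1 FPKM, at about 1.015 and 1.020, whereas 4732 genes above 20 FPKM sat at 1.017. For each low gene near the latter ratio there were 2.33 near the lower peak, but the upper peak was weaker, with 448 low genes against 379 near that ratio. The peaks may come from 2 libraries, each scaled by its own factor, averaged into each value, with low genes often read in only 1 of them, but the weak upper peak and the lack of values per library leave this open. No biological explanation was tested.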
